A study of Mus musculus with 48 samples.

How the data were processed

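RNA abundance was measured in whole lungs of 48 male C57BL/6 mice with 1 Affymetrix microarray per animal. The animals formed 6 groups of 8, given by diet (regular weight or diet-induced obese) and by what they breathed (filtered air, mainstream smoke or sidestream smoke). In the names of single arrays, RW and DIO stand for regular weight and diet-induced obese animals, SC, MS and SS for filtered air, mainstream and sidestream smoke, and the last number for the animal. The deposited sources of RW-MS-7, RW-MS-8, RW-SS-7 and RW-SS-8 repeat the numbers 5 and 6, and these arrays were taken as separate animals. The deposited values are log2 signals that the authors made with RMA, a method that subtracts background, quantile normalizes the arrays given to it and summarizes the probes of each probe set. The version of RMA, the software that ran it and whether all 48 arrays were normalized together are not given in the sources used here. The deposited values lay between 2.50 and 15.3, and the medians of the arrays lay between 7.82 and 7.94. No raw scans were used here, so the background correction and the summary of probes could not be changed.

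The deposited table held 22690 probe sets, of which 64 were hybridization controls. Of the 21084 probe sets with an entry in the annotation of the array, 20393 carried 1 gene symbol and 691 several, and 1606 probe sets had no entry. A total of 20380 probe sets with 1 symbol were used. The Entrez number of 20351 of these was found in a table of mouse gene names of assembly GRCm38.p6, and 0 symbols changed through it. Where a gene had several probe sets, as 4956 genes did, the one with the highest mean over the 48 arrays stood for it, which left 12393 genes. Probe sets that the manufacturer marks as able to match more than 1 transcript were kept, and no dim gene was left out. The 2246 probe sets without exactly 1 symbol were tested apart from the genes.

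Each gene was fitted with a mean per group over all 48 arrays in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes without trend and not robust), and tables were handled with the package data.table, version 1.17.8. P values were adjusted by the Benjamini-Hochberg method over the 12393 genes within each of 9 contrasts. The contrasts were obese against regular weight animals in air, mainstream and sidestream smoke against air within each diet, the difference between the diets in the response to each smoke, and mainstream against sidestream smoke within each diet. All tests were two-sided, and a gene was called changed at an adjusted p below 0.05. The error given with a log2 difference is its standard error from this model. Beside it stands the number of arrays of a group that lay beyond every array of its reference group.

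A total of 36 gene lists were tested. They covered defence against oxidants and xenobiotics (NRF2 targets, glutathione transferases, aryl hydrocarbon receptor targets, pulmonary xenobiotic enzymes) and inflammation (chemokines and cytokines, acute phase genes, interferon response). Further lists held markers of neutrophils, alveolar macrophages, T cells, B cells and NK cells, lipid and lysosome genes of macrophages, and MHC class II and dendritic cell genes. Lists of cell state held clock genes peaking with Dbp, clock genes peaking with Bmal1, glucocorticoid and restraint stress genes, immediate early genes, heat shock genes, the unfolded protein response, p53 targets and cell cycle genes. Lists of metabolism held fatty acid oxidation, fatty acid synthesis and cholesterol synthesis. Lists of tissue held markers of type 2 and type 1 alveolar cells, club and goblet cells, ciliated cells, endothelium, smooth muscle, and matrix genes of fibroblasts. Markers of tissues that a lung sample can carry with it were adipocyte, cardiac muscle, skeletal muscle and red cell markers.

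Each list was tested with fry from limma over all 324 pairs of list and contrast, with Benjamini-Hochberg adjustment over the 324. The p of fry that was used asks whether the members move, on balance, in 1 direction, its mixed p asks whether they change in either direction, and neither compares the list with other genes. Each list was also tested with camera, once with the correlation between members estimated from the data and once with a preset correlation of 0.01. The count of members called is given over all genes and also adjusted over the list alone. Thymocyte, squamous epithelium and brown fat markers were added later, as scores for single arrays. A list score of an array is the mean over members of the deviation from the mean of each gene.

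The size of the obese response relative to the regular weight response was the sum of the signed changes in obese animals over the sum in regular weight animals. It was taken over genes called for the mean of both diets and tested with fry on the difference between the diets, with the signs as gene weights and adjustment over the 2 smokes. Correlations of responses were taken across the 12393 genes, which are not independent replicates. Responses to mainstream and sidestream smoke within a diet share their air arrays. Their correlation was therefore also taken with the air arrays dealt 4 and 4 to the 2 smokes in 100 splits, and in 100 simulated sets of unchanged groups (seed 1).

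The genes named in the results followed a rule. For the 5 contrasts against a control group it took the 8 highest and 8 lowest log2 changes among called genes, and for the other 4 contrasts the 6 highest and 6 lowest. For each list described it took up to 4 called members with the largest change, or the 2 members with the smallest p where none was called. In every contrast it took the indicator genes Cyp1a1, Cyp1b1, Nqo1, Gclc, Hmox1, Mmp12, Ccl2, S100a8, Scd1, Adipoq and Dbp. Predicted genes were counted but not named. The tests, the 36 lists, this rule and the alternative settings were chosen before the data were examined.

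The alternatives were a second quantile normalization, centring each array on its median, leaving out the dimmest 40% of genes, the mean of the probe sets of a gene, every probe set on its own, and a fit to the groups of each contrast alone. Others were eBayes with trend, eBayes with trend and robust, array weights, a replicate block, leaving out each array in turn, genes past 1.5-fold for the ratio of sizes, and both forms of camera. Leaving out 5 arrays that stand apart was added after the data had been seen.

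The steps were also tested on 1 simulation with 12393 genes for each of the 9 contrasts. Of 50 genes changed 1.25-fold, between 28% and 72% were recovered, of 50 changed 1.5-fold between 78% and 98%, and of 50 changed 2-fold between 82% and 100%. Of 3 lists shifted by 0.3, 1 was recovered for diet and for mainstream against sidestream smoke in regular weight animals and 2 or 3 in the other simulations. Of 33 lists not shifted, 2 moved in the simulation of the mainstream difference between the diets and 0 in the others. Of genes left unchanged, 394 were called for sidestream smoke against air in regular weight animals and at most 12 in the others (mainstream smoke, obese animals). For the size of the mainstream response a true ratio of 1.3 was fitted as 1.32 over 306 selected of the 12393 genes.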

Results

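Gene expression was measured in the lungs of 48 male mice, with 8 animals in each of 6 groups. Regular weight animals ate a diet with about 5 kcal% fat. Obese animals ate a diet with 60 kcal% fat from 6 weeks of age and had done so for 9 weeks when exposure began. Animals of each diet breathed filtered air, mainstream smoke (the smoke drawn through the cigarette) or sidestream smoke (the smoke given off by the burning tip). They did so through the nose alone, 5 hours a day on 8 days spread over 2 weeks, and the lungs were collected 1 day later. The deposited description of the animals also mentions a study of 4 days with LPS, so whether any animal had another treatment is left open. The title of the series asks about obesity and the inflammatory and oxidative stress responses to cigarette smoke. A value after ± is a standard error on the log2 scale unless SD is written, every group had n = 8, and each gene's p is limma's and each list's p is fry's, adjusted as described. The medians of all 12393 genes lay between -0.04 and 0.03 in the 9 contrasts.

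In filtered air Mmp12, a macrophage elastase, had a log2 signal of 6.75 ± 0.16 (SD, n = 8) in regular weight and 6.44 ± 0.41 in obese animals. Cyp1a1, the classic target gene of the aryl hydrocarbon receptor, had 9.58 ± 0.41 and 4.74 ± 0.33. Dbp, an output gene of the circadian clock, had 11.59 ± 0.20 and 11.39 ± 0.21.

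**Figure D1:**
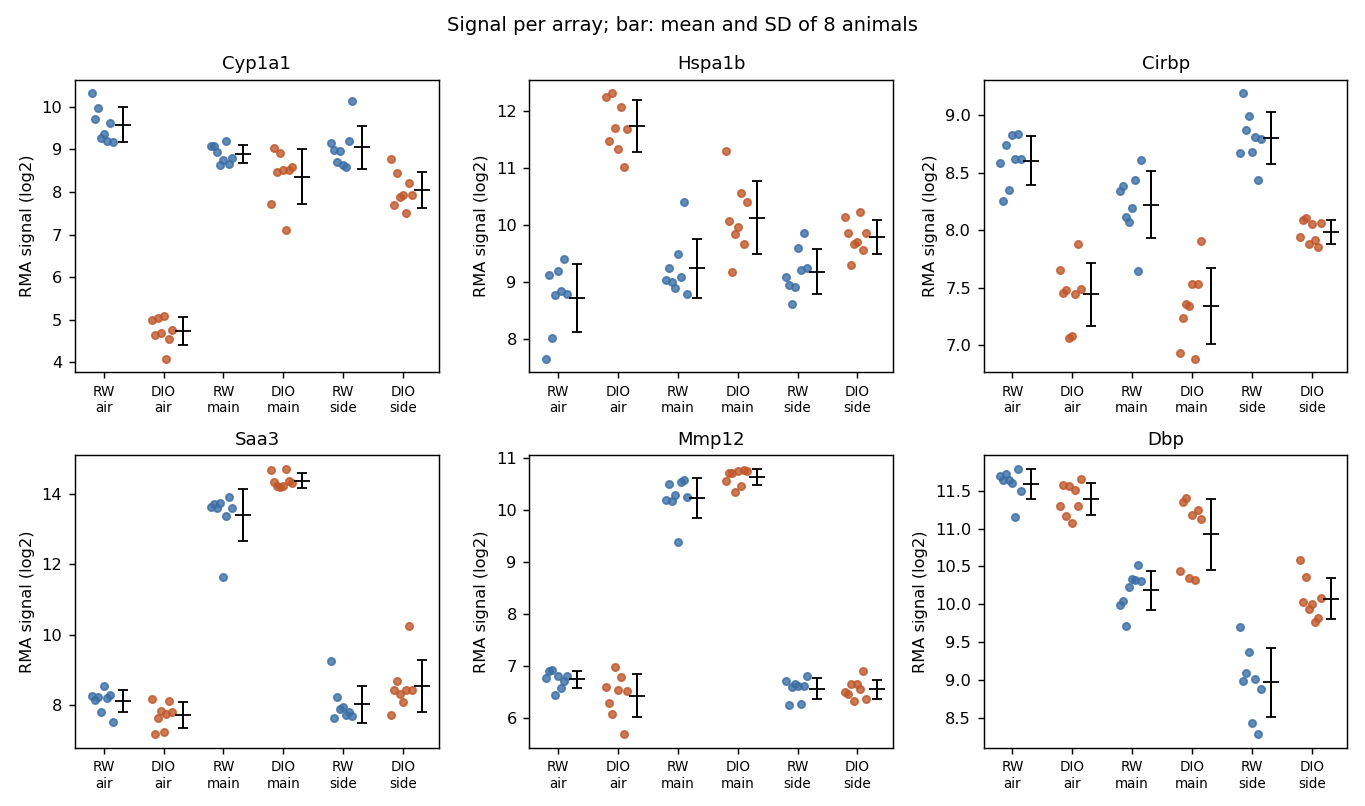
Log2 RMA signal (vertical axis) of Cyp1a1, Hspa1b, Cirbp, Saa3, Mmp12 and Dbp in each of the 48 lungs, by group (horizontal axis), with the bar and whiskers giving the mean and SD of 8 animals. Cyp1a1 averaged 4.74 in obese animals breathing air and between 8.05 and 9.58 in the other 5 groups.

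A set of 5 arrays stood apart, with mean correlations to the others of 0.963 to 0.982 against at least 0.987 for the remaining 43. Array DIO-SC-3 held transcripts of skeletal muscle and squamous epithelium, such as Tnnc2 (9.13 log2 above the rest of its group), Krtdap (8.80) and Krt4 (8.30). Array DIO-SC-7 held transcripts of thymus and brown fat, such as Rag1 (8.85), Ucp1 (8.47) and Dntt (6.32). Array RW-SS-6 held transcripts of fat, such as Ucp1 (8.29), Pck1 (6.98) and Adipoq (5.46). Arrays DIO-MS-1 and DIO-MS-6 held genes induced by interferon, such as Cxcl9 (5.48 and 5.23), Cxcl10 (5.22 and 5.22) and Mx1 (4.87 and 4.55). These named genes were chosen after their values had been seen. RNA quality moved little with the groups, as the 3′ minus 5′ signal of Actb was 0.39 ± 0.13 (SD, n = 8) in regular weight animals breathing air and between 0.39 and 0.51 in the other 5 groups.

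**Figure D2:**
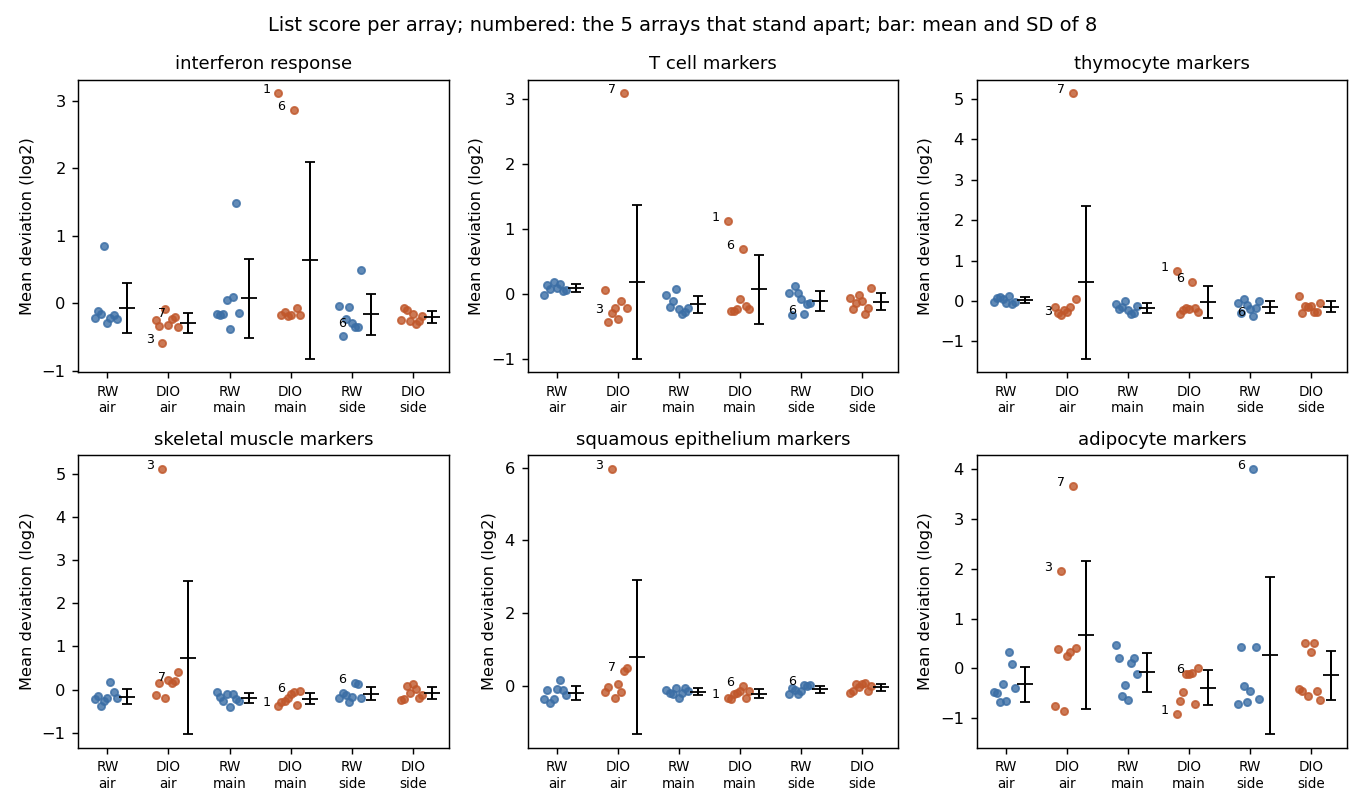
Score of 6 marker lists on each array (vertical axis, mean log2 deviation of the members from their mean over 48 arrays), by group (horizontal axis), with the bar and whiskers giving the mean and SD. The 5 numbered arrays stand apart, with a skeletal muscle score of 5.12 on DIO-SC-3 and a thymocyte score of 5.15 on DIO-SC-7.

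The air groups were compared to ask what the diet did without smoke. Cyp1a1 was 28.6-fold lower in obese than in regular weight animals (log2 -4.84 ± 0.21, n = 8, adjusted p = 2.1e-22), and all 8 obese arrays lay below all 8 regular weight arrays. Hspa1b and Hspa1a, the stress-inducible Hsp70 chaperones, were 8.03-fold (3.01 ± 0.24) and 4.88-fold (2.29 ± 0.20) higher, each on 8 of 8 arrays. Cirbp, an RNA-binding protein induced by mild cold, was 2.24-fold lower (-1.16 ± 0.12, 8 of 8 arrays).

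All 13 measured heat shock genes rose over all genes and adjusted over the list alone (median 0.63, adjusted p = 1.6e-16). Hsph1 and Dnaja1, a co-factor and a co-chaperone of Hsp70, rose by 1.52 ± 0.12 and 1.07 ± 0.09. Among 11 B cell markers 8 fell (9 adjusted over the list alone, median -0.62, adjusted p = 3.7e-09). Examples were Cd79b at -1.0 ± 0.12, the low-affinity IgE receptor Fcer2a at -1.0 ± 0.15 and Ms4a1, the gene of CD20, at -0.98 ± 0.14. Of 9 MHC class II and dendritic cell genes 6 fell (7 adjusted over the list alone, median -0.33, adjusted p = 2.5e-04), including H2-DMa (-0.48 ± 0.11) and H2-Eb1 (-0.40 ± 0.08). Their call was lost at adjusted p = 0.13 with an estimated correlation.

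The call of 7 aryl hydrocarbon receptor targets (median -0.09, mean -0.66, adjusted p = 1.8e-09) came from Cyp1a1 alone, the 1 member called over all genes and adjusted over the list alone. It was lost at adjusted p = 0.20 with an estimated correlation, and Cyp1b1 differed by -0.18 ± 0.14 (adjusted p = 0.50). Glucocorticoid and restraint stress genes moved upward (median 0.13, adjusted p = 0.012), with 4 of 14 higher and 1 lower (5 and 1 adjusted over the list alone). Zbtb16 at 1.27 ± 0.27 and Fkbp5 at 0.99 ± 0.15 rose on 8 of 8 arrays. With an estimated correlation the list had adjusted p = 0.11. Of 12 p53 targets 3 rose (3 higher and 1 lower adjusted over the list alone, median 0.13, adjusted p = 2.3e-04), among them Ccng1 at 0.36 ± 0.09. Of 5 clock genes peaking with Bmal1, Nfil3 rose by 0.44 ± 0.13 (2 adjusted over the list alone, median 0.22, adjusted p = 0.0025, and adjusted p = 0.094 with an estimated correlation, with a median of 0.10 without the 5 arrays). The clock genes peaking with Dbp had a median of -0.05 (adjusted p = 0.83). The unfolded protein response list moved upward (median 0.10, adjusted p = 0.044) with 3 of 14 higher, such as Hspa5 at 0.30 ± 0.07, and 1 lower, both over all genes and adjusted over the list alone. Its call was lost at adjusted p = 0.25 with an estimated correlation, and its median was 0.16 without the 5 arrays.

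Smooth muscle markers rose in 8 of 9 cases (9 adjusted over the list alone, median 0.44, adjusted p = 5.5e-04), such as Actg2 at 0.74 ± 0.18. They had adjusted p = 0.052 with an estimated correlation. Alveolar type 2 markers fell in 5 of 11 cases (9 adjusted over the list alone, median -0.23, adjusted p = 0.0051, and adjusted p = 0.33 with an estimated correlation). Etv5, a transcription factor of these cells, fell by 0.53 ± 0.11, and without the 5 arrays that stand apart 3 of the 5 were still called and the median of the list was -0.08. Fatty acid oxidation genes rose in 3 of 16 cases (10 adjusted over the list alone, median 0.43, adjusted p = 0.046, and adjusted p = 0.28 with an estimated correlation), led by Pdk4 at 1.68 ± 0.41 and Fabp3 at 1.35 ± 0.43. Without the 5 arrays their median was 0.12 and the list and Fabp3 lost their calls, while Pdk4 was 0.97 higher. The muscle genes Acta1 (1.99 ± 0.59, 6 of 8 arrays), Myl1 (1.92 ± 0.53), Tnnt3 (1.60 ± 0.50) and Ckm (1.45 ± 0.47) were called, and without the 5 arrays their differences were 1.04, 1.03, 0.89 and 0.78, the last not called. The skeletal muscle list (3 of 11 higher, also adjusted over the list alone, median 0.77, adjusted p = 0.085, and adjusted p = 0.045 with a median of 0.06 without the 5 arrays) and the adipocyte list (2 of 10 higher, 3 adjusted over the list alone, median 0.99, adjusted p = 0.093) did not move as wholes. Cardiac muscle markers did not either (median 0.69, adjusted p = 0.17). T cell markers had a median of 0.15 (adjusted p = 0.83) with DIO-SC-7 at a score of 3.10 against at most 0.06 in the other 7 obese air arrays, and without the 5 arrays the list turned downward and was called (median -0.26, adjusted p = 2.4e-04).

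In all, 1026 of 12393 genes were called, 284 higher and 742 lower in obese animals, and 93 of them passed 1.5-fold. Of the 36 lists 11 moved. Without the 5 arrays 1183 genes were called, 431 of them higher.

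**Figure D3:**
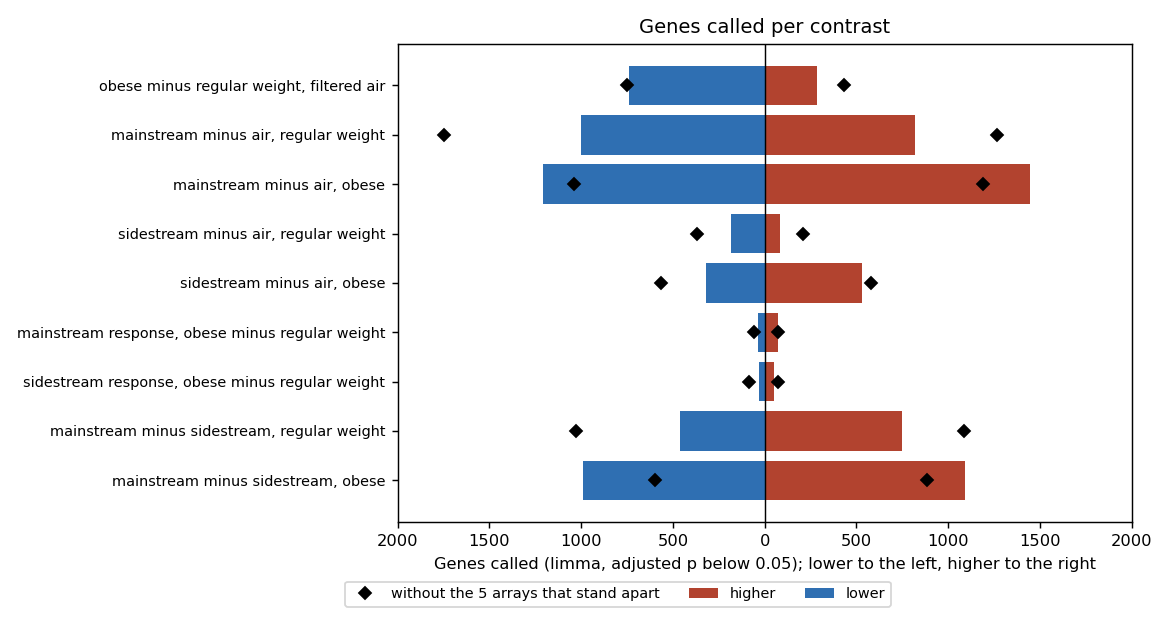
Number of genes called higher (right, red) and lower (left, blue) in each of the 9 contrasts, with diamonds for the counts without the 5 arrays that stand apart. Mainstream smoke against air called 1819 genes in regular weight and 2658 in obese animals, and sidestream smoke 269 and 849.

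Mainstream smoke was compared with air in regular weight animals to measure the response without obesity. Saa3, an acute phase protein made locally in inflamed tissue, was 38.8-fold higher (5.28 ± 0.25, n = 8, adjusted p = 2.1e-21, 8 of 8 arrays). The neutrophil-attracting chemokines Cxcl5 and Cxcl1 were 20.2-fold (4.34 ± 0.34) and 12.9-fold (3.69 ± 0.24) higher. The macrophage elastase Mmp12 was 11.3-fold (3.49 ± 0.13) and the cathepsin Ctsk 7.92-fold (2.99 ± 0.10) higher. The anion exchanger Slc26a4, the antigen Ly6i and the siderophore-binding Lcn2 rose by 3.64 ± 0.20, 3.43 ± 0.24 and 2.70 ± 0.12. Among the lowest were the peroxisomal thiolase Acaa1b (-2.46 ± 0.16), the fatty acid binding protein Fabp1 (-2.33 ± 0.20) and the clock repressor Nr1d1 (-2.03 ± 0.12), each below the air range on 8 of 8 arrays.

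Chemokines and cytokines rose in 14 of 20 cases (15 adjusted over the list alone, median 1.17, adjusted p = 2.9e-07), including Ccl2 at 2.40 ± 0.28. Acute phase genes rose in 11 of 14 cases (11 adjusted over the list alone, median 1.06, adjusted p = 5.6e-14), such as Timp1 at 2.23 ± 0.20. Lipid and lysosome genes of macrophages rose in 10 of 14 cases and fell in 1 (11 and 1 adjusted over the list alone, median 0.60, adjusted p = 8.8e-18), with Gpnmb at 2.52 ± 0.13 and Cd68 at 1.36 ± 0.09. Alveolar macrophage markers went both ways, with 4 of 12 higher and 3 lower (the same counts adjusted over the list alone), among them Ctsk and the scavenger receptor Marco (1.98 ± 0.16). That list had a median of 0.02 and adjusted p = 6.1e-04, lost at adjusted p = 0.60 with an estimated correlation. Neutrophil markers did not move as a list (median 0.10, adjusted p = 0.23, and adjusted p = 0.0090 without the 5 arrays), although Clec4d (1.26 ± 0.19) and Mmp8 (1.22 ± 0.18) rose, and S100a8 differed by 0.13 ± 0.21. Cell cycle genes rose in 12 of 21 cases (17 adjusted over the list alone, median 0.77, adjusted p = 0.016), with Mki67 at 1.47 ± 0.33. They had adjusted p = 0.35 with an estimated correlation. B cell markers fell in 5 of 11 cases (7 adjusted over the list alone, median -0.37, adjusted p = 0.0014, and adjusted p = 0.30 with an estimated correlation), such as Ms4a1 at -0.70 ± 0.14.

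Clock genes peaking with Dbp fell in 8 of 10 cases (8 adjusted over the list alone, median -0.58, adjusted p = 5.7e-10), with Dbp at -1.41 ± 0.16. The clock genes peaking with Bmal1 rose in 4 of 5 cases (4 adjusted over the list alone, median 0.32, adjusted p = 4.1e-07), such as Arntl, the gene of Bmal1, at 0.53 ± 0.15. Cholesterol synthesis genes rose in 10 of 15 cases (11 adjusted over the list alone, median 0.35, adjusted p = 2.9e-07), with Cyp51 at 0.72 ± 0.09. Matrix genes rose in 11 of 13 cases (11 adjusted over the list alone, median 0.60, adjusted p = 9.2e-07), with the gelatinase Mmp2 at 1.04 ± 0.08 and collagen Col3a1 at 0.81 ± 0.13.

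Cyp1a1 fell by 0.69 ± 0.21 (adjusted p = 0.022, 7 of 8 arrays) while Cyp1b1 rose by 0.58 ± 0.14 (adjusted p = 0.0040, 8 of 8 arrays), and the receptor's list as a whole did not move (median 0.05, adjusted p = 0.51). NRF2 targets did not move as a list (3 of 18 higher and 2 lower, 4 and 3 adjusted over the list alone, median 0.05, adjusted p = 0.33). Among them Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis, rose by 0.56 ± 0.13 and the cystine transporter Slc7a11 by 0.62 ± 0.17. Nqo1 and Hmox1 differed by -0.04 ± 0.12 and 0.21 ± 0.12 (adjusted p = 0.87 and 0.28). Pulmonary xenobiotic enzymes fell in 4 of 10 cases (5 adjusted over the list alone, median -0.23, adjusted p = 0.023, and adjusted p = 0.52 with an estimated correlation), such as Fmo2 at -0.63 ± 0.14. Glutathione transferases had a median of -0.08 (adjusted p = 0.12, and 2.2e-04 without the 5 arrays), with 4 of 17 lower (5 adjusted over the list alone). Endothelial markers fell in 6 of 16 cases (8 adjusted over the list alone, median -0.22, adjusted p = 0.026) and alveolar type 1 markers in 2 of 7 (4 adjusted over the list alone, median -0.22, adjusted p = 0.043), such as Ramp2 and the water channel Aqp5 (-0.53 and -0.35). These 2 calls were lost at adjusted p = 0.52 and adjusted p = 0.56 with an estimated correlation.

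Upward movement of glucocorticoid and restraint stress genes was called (5 of 14 higher and 2 lower, the same adjusted over the list alone, median 0.08, mean 0.26, adjusted p = 2.3e-04, and adjusted p = 0.32 with an estimated correlation), with Sgk1 at 0.65 ± 0.09. Lcn2 at 2.70, which is also an acute phase gene, gave most of that mean. Of 12 p53 targets 4 rose (4 adjusted over the list alone, median 0.10, adjusted p = 1.2e-04, and adjusted p = 0.052 with an estimated correlation), led by Cdkn1a at 0.60 ± 0.16. The interferon (median 0.07, adjusted p = 0.83) and heat shock lists (0.02, adjusted p = 0.69) did not move.

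Mainstream smoke called 1819 genes in regular weight animals, 819 higher and 1000 lower, and 15 lists moved. Centring each array on its median turned the balance to 959 higher of 1719, and 3015 genes were called without the 5 arrays, none of which is in these groups though all enter the pooled spread.

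**Figure D4:**
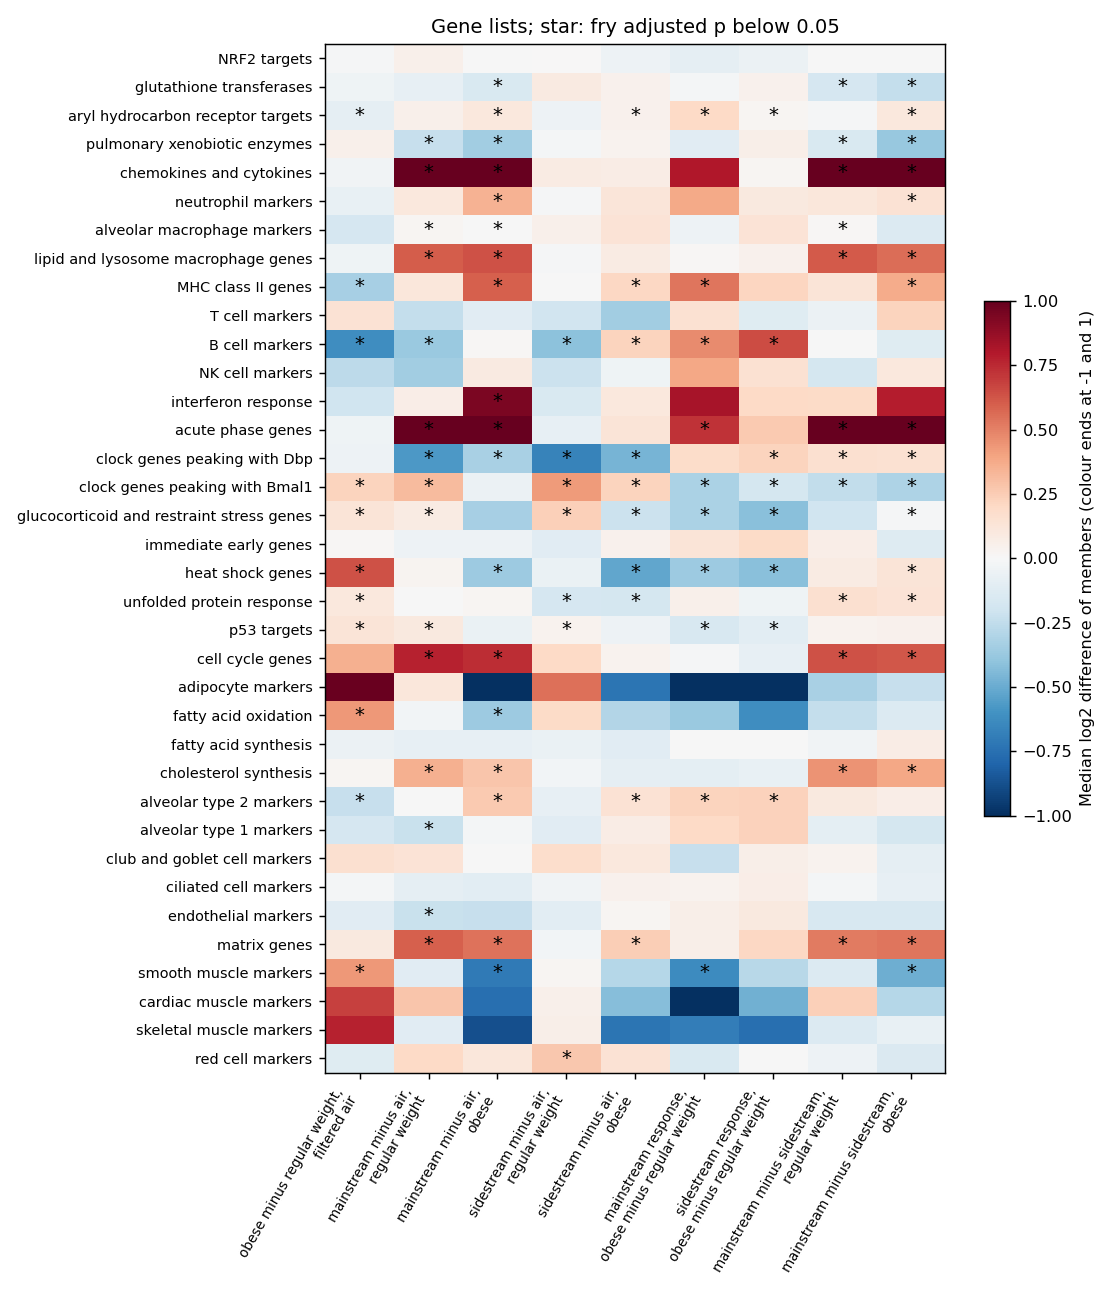
Median log2 change of each of the 36 gene lists (vertical axis) in the 9 contrasts (horizontal axis), coloured from -1 or below (blue) to 1 or above (red), with a star where fry called the list moved. Acute phase genes had medians of 1.06 and 1.99 under mainstream smoke in regular weight and obese animals.

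The same comparison in obese animals measured the response on the high fat diet. Saa3 was 101-fold higher (6.66 ± 0.25, n = 8, adjusted p = 1.2e-25, 8 of 8 arrays), and Cxcl5 and Cxcl1 were 25.2-fold (4.66 ± 0.34) and 23.6-fold (4.56 ± 0.24) higher. Mmp12 and Lcn2 were 18.4-fold (4.21 ± 0.13) and 10-fold (3.32 ± 0.12) higher. Cyp1a1 was 12.3-fold higher (3.62 ± 0.21, adjusted p = 1.4e-18, 8 of 8 arrays). Acaa1b and Fabp1 were 7.99-fold (-3.0 ± 0.16) and 6.87-fold (-2.78 ± 0.20) lower, and Zbtb16, a transcription factor induced by glucocorticoids, was 4.15-fold lower (-2.05 ± 0.27).

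Chemokines and cytokines rose in 19 of 20 cases (19 adjusted over the list alone, median 2.12, adjusted p = 5.1e-12, and a median of 1.39 without the 5 arrays), with the macrophage chemokine Ccl3 at 3.22 ± 0.30 and Ccl2 at 3.10 ± 0.28. Acute phase genes rose in 13 of 14 cases (13 adjusted over the list alone, median 1.99, adjusted p = 4.1e-20), with Timp1 at 3.15 ± 0.20. Lipid and lysosome genes of macrophages rose in 10 of 14 cases and fell in 1 (the same adjusted over the list alone, median 0.63, adjusted p = 8.5e-18), with Gpnmb at 2.14 ± 0.13. Neutrophil markers rose in 7 of 14 cases (7 adjusted over the list alone, median 0.35, adjusted p = 6.8e-04, and adjusted p = 0.35 with an estimated correlation), such as Mmp8 at 1.79 ± 0.18. They did so largely with arrays DIO-MS-1 and DIO-MS-6, whose scores were 1.12 and 1.3 against 0.09 to 0.20 in the other 6, and without the 5 arrays 4 were called and the median was -0.01. MHC class II genes rose in 8 of 9 cases and fell in 1 (the same adjusted over the list alone, median 0.60, adjusted p = 3.0e-08, and adjusted p = 0.052 with an estimated correlation), with H2-Ab1 at 0.74 ± 0.08 and their transactivator Ciita at 0.67 ± 0.13. DIO-MS-1 and DIO-MS-6 scored 0.54 and 0.45 against 0.11 to 0.24 in the other 6, and the median was 0.52 without the 5 arrays. Alveolar macrophage markers had 4 of 12 higher and 5 lower (the same adjusted over the list alone), a median of -0.01 and an upward test (adjusted p = 0.0045, and adjusted p = 0.93 with an estimated correlation), with Marco at 1.46 ± 0.16 and Cidec at -1.91 ± 0.36. Interferon response genes rose in 8 of 16 cases (15 adjusted over the list alone, median 0.94, adjusted p = 0.029, and adjusted p = 0.55 with an estimated correlation), such as Ifit1 at 1.37 ± 0.43. The rise came with arrays DIO-MS-1 and DIO-MS-6, whose scores were 3.11 and 2.86, while the highest score of the other 6 obese mainstream arrays was -0.07. The median was 0.14 and the call of the list was lost without the 5 arrays.

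Heat shock genes fell in 10 of 13 cases (11 adjusted over the list alone, median -0.36, adjusted p = 3.7e-08), with Hspa1b at -1.61 ± 0.24. All 9 smooth muscle markers fell, also adjusted over the list alone (median -0.71, adjusted p = 1.6e-07, and adjusted p = 0.053 with an estimated correlation), with Cnn1 at -1.15 ± 0.18. The lowest smooth muscle scores were those of DIO-MS-1 and DIO-MS-6 (-0.97 and -0.52), and the median was -0.49 without the 5 arrays. Other tissue that a lung can carry had lower mean scores too, 0.52 in air and -0.23 under smoke for cardiac muscle (list median -0.75, adjusted p = 0.16, DIO-MS-1 lowest at -2.24) and 0.81 and -0.42 for brown fat, so a difference in carried tissue is not excluded. Clock genes peaking with Dbp fell in 7 of 10 cases (8 adjusted over the list alone, median -0.33, adjusted p = 3.2e-05, and adjusted p = 0.20 with an estimated correlation), with Nr1d1 at -1.13 ± 0.12. DIO-MS-1 and DIO-MS-6 scored -0.31 and -0.41 against 0.07 to 0.32 in the other 6, and the median was -0.24 without the 5 arrays. The clock genes peaking with Bmal1 did not move (median -0.06, adjusted p = 0.37). Matrix genes rose in 10 of 13 cases (11 adjusted over the list alone, median 0.54, adjusted p = 2.9e-07, and adjusted p = 0.066 with an estimated correlation), with Lox at 1.11 ± 0.13. Cholesterol synthesis genes rose in 11 of 15 cases (11 adjusted over the list alone, median 0.27, adjusted p = 1.3e-04, and adjusted p = 0.23 with an estimated correlation), such as Mvd at 0.52 ± 0.08. Cell cycle genes rose in 14 of 21 cases (18 adjusted over the list alone, median 0.74, adjusted p = 0.016, and adjusted p = 0.51 with an estimated correlation), such as Cdk1 at 1.23 ± 0.29 with 0 of 8 arrays above the air range. Array DIO-SC-7 raised the air mean, with a score of 2.46 against -0.61 to -0.30 in the other 7, and without the 5 arrays 20 were called and the median was 0.92. Alveolar type 2 markers rose in 6 of 11 cases (7 adjusted over the list alone, median 0.27, adjusted p = 0.0012, and adjusted p = 0.42 with an estimated correlation), with Sftpd at 0.70 ± 0.06, and the median was 0.12 without the 5 arrays.

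The 7 receptor targets moved upward (median 0.11, adjusted p = 9.8e-11), with 2 called, also adjusted over the list alone. They were Cyp1a1 and Cyp1b1 (1.03 ± 0.14, 2 of 8 arrays above an air range set by DIO-SC-7). Pulmonary xenobiotic enzymes fell in 6 of 10 cases (8 adjusted over the list alone, median -0.34, adjusted p = 5.5e-04) and glutathione transferases in 6 of 17 (1 higher and 6 lower adjusted over the list alone, median -0.15, adjusted p = 0.030), with Fmo2 at -0.65 ± 0.14 and Gstk1 at -0.45 ± 0.08. With an estimated correlation they had adjusted p = 0.29 and adjusted p = 0.56. DIO-MS-1 and DIO-MS-6 scored lowest on both (-0.75 and -0.70 for the xenobiotic enzymes, -0.50 and -0.51 for the transferases), and the medians were -0.26 and -0.12 without the 5 arrays. NRF2 targets had 2 of 18 higher and 6 lower (the same adjusted over the list alone) and did not move as a list (median -0.0035, adjusted p = 0.18). Slc7a11 rose by 0.83 ± 0.17, and Gclc rose by 0.51 ± 0.13, with 0.23 and no call without the 5 arrays. Nqo1 was called at -0.32 ± 0.12 and was 0.02 without the 5 arrays. Fatty acid oxidation genes fell in 7 of 16 cases (7 adjusted over the list alone, median -0.36, adjusted p = 0.043, and adjusted p = 0.56 with an estimated correlation), led by Pdk4 at -1.62 ± 0.41, and without the 5 arrays the median was -0.06 and the call was lost.

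Mainstream smoke called 2658 genes in obese animals, 1448 higher and 1210 lower, and 18 lists moved.

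The difference between the diets in the mainstream response was tested directly, which is the question named in the title. The response of Cyp1a1 was 19.8-fold greater in obese animals (4.31 ± 0.30, n = 8 per group, adjusted p = 2.1e-14), where the gene started from a lower level in air. The acute phase genes Orm2 (1.42 ± 0.36), Saa3 (1.38 ± 0.36, adjusted p = 0.046) and Saa1 (1.35 ± 0.21, adjusted p = 3.9e-04) and the haem-binding protein Hpx (1.09 ± 0.18) rose more in obese animals. Hspa1b (-2.12 ± 0.34, adjusted p = 3.9e-04), Hspa1a (-1.77 ± 0.28) and Zbtb16 (-1.59 ± 0.38) changed in the downward direction relative to regular weight animals.

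Of 14 acute phase genes 5 differed upward (9 adjusted over the list alone, median 0.72, adjusted p = 1.2e-04). Arrays DIO-MS-1 and DIO-MS-6 had acute phase scores of 2.11 and 2.24 against 1.09 to 1.3 in the other 6, and without the 5 arrays 2 genes were called and the median was 0.37. Upward differences were also called for 6 of 9 MHC class II and dendritic cell genes (8 adjusted over the list alone, median 0.53, adjusted p = 9.2e-05), such as Ccr7 at 0.92 ± 0.21 and H2-Eb1 at 0.54 ± 0.12, with a median of 0.45 and 3 called without the 5 arrays. B cell markers differed upward in 2 of 11 cases (8 adjusted over the list alone, median 0.47, adjusted p = 8.4e-04), with Fcer2a at 1.08 ± 0.21 and Blnk at 0.55 ± 0.14. Heat shock genes differed downward in 5 of 13 cases (9 adjusted over the list alone, median -0.36, adjusted p = 7.9e-06) and smooth muscle markers in 5 of 9 (9 adjusted over the list alone, median -0.63, adjusted p = 8.2e-04), such as Actg2 at -1.04 ± 0.25, with a median of -0.37 and 1 called without the 5 arrays. The air groups themselves differed in the opposite direction for both lists, with medians of 0.63 and 0.44. Glucocorticoid and restraint stress genes (1 of 14 lower, 1 higher and 6 lower adjusted over the list alone, median -0.32, adjusted p = 0.0076) and p53 targets (1 of 12 lower, 1 higher and 2 lower adjusted over the list alone, median -0.16, adjusted p = 1.5e-04) differed downward. So did the clock genes peaking with Bmal1 (4 of 5 lower adjusted over the list alone and none over all genes, median -0.32, adjusted p = 1.2e-05), where Arntl had -0.73 ± 0.22. Dbp and Nr1d1 differed upward by 0.95 ± 0.23 and 0.89 ± 0.17. The receptor's list (median 0.20, adjusted p = 1.4e-06) rested on Cyp1a1 alone of 7, also adjusted over the list alone. Alveolar type 2 markers differed upward in 1 of 11 cases, Etv5 at 0.70 ± 0.15 (5 adjusted over the list alone, median 0.22, adjusted p = 0.026, and adjusted p = 0.28 with an estimated correlation, with a median of 0.11 without the 5 arrays).

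Chemokines and cytokines had a median difference of 0.80 (5 of 20 higher adjusted over the list alone, adjusted p = 0.058), which was 0.19 without the 5 arrays, as DIO-MS-1 and DIO-MS-6 scored 3.10 and 3.47 against 0.79 to 1.07 in the other 6. The median was -0.09 for NRF2 targets (adjusted p = 0.071) and -0.01 for cell cycle genes (adjusted p = 0.99, and 0.18 with adjusted p = 0.38 without the 5 arrays). Ccl2, Gclc and Hmox1 differed by 0.70 ± 0.39, -0.05 ± 0.18 and 0.05 ± 0.18 (adjusted p = 0.43, 0.95 and 0.94). Mmp12 differed by 0.71 ± 0.19 (adjusted p = 0.048). Orm2 differed by 0.77 without the 5 arrays, and Saa3 (1.33), Mmp12 (0.57) and Blnk (0.47) then lost their calls. In all 110 genes were called, 73 higher and 37 lower, and 10 lists moved. Centring each array gave 94 genes with 47 higher.

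Over the 3659 genes called for the mean of both diets, the mainstream response in obese animals was 1.31 times as large as in regular weight animals (mean signed log2 change 0.363 against 0.277). It was larger in obese animals for 2278 genes (62.3%), and fry on the difference between the diets gave adjusted p = 0.10. Over the alternatives this p lay between 0.0082, with a ratio of 1.39 over the 368 genes past 1.5-fold, and 0.42, with a ratio of 1.1 without the 5 arrays. Across genes the 2 responses had r = 0.70 and rho = 0.51, and 603 genes were called higher and 380 lower in both, against 95.7 and 97.6 by chance, with 12 called in opposite directions.

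**Figure D5:**
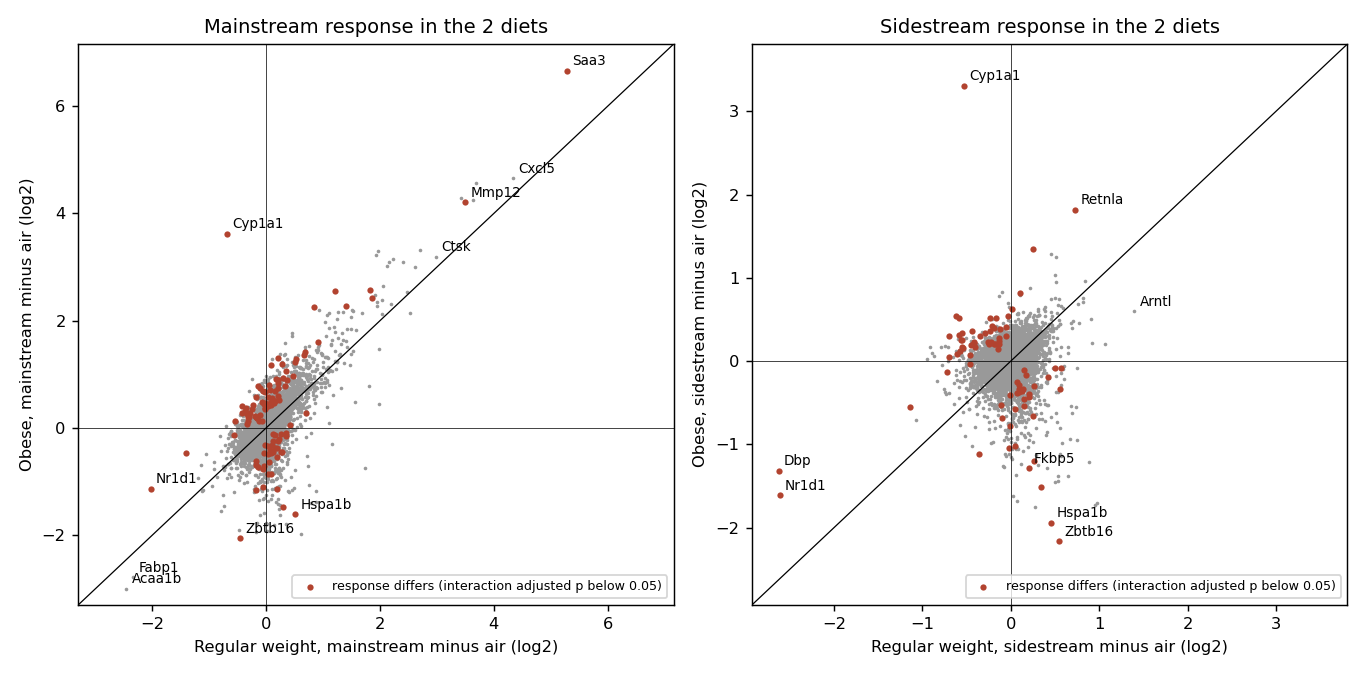
Log2 change under mainstream (left) and sidestream smoke (right) in regular weight (horizontal axis) against obese animals (vertical axis), 1 point per gene, with red points for genes whose response differed between the diets. Red points number 110 for mainstream and 81 for sidestream smoke, with Cyp1a1 at -0.69 and 3.62 under mainstream smoke.

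Sidestream smoke was compared with air in regular weight animals. Dbp was 6.17-fold lower (-2.62 ± 0.16, n = 8, adjusted p = 6.2e-17, 8 of 8 arrays), and the clock repressors Nr1d1 and Nr1d2 were 6.12-fold (-2.61 ± 0.12) and 2.20-fold (-1.14 ± 0.08) lower. Arntl, their antiphase partner in the clock, was 2.63-fold higher (1.40 ± 0.15, 8 of 8 arrays), and Nfil3 rose by 0.92 ± 0.13. Cyp1b1 rose by 0.60 ± 0.14 on 8 of 8 arrays (adjusted p = 0.016), and Cyp1a1 had -0.53 ± 0.21 (adjusted p = 0.19).

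Clock genes peaking with Dbp fell in 6 of 10 cases (9 adjusted over the list alone, median -0.67, adjusted p = 1.3e-14), including Per3 at -0.72 ± 0.09, and those peaking with Bmal1 rose in 4 of 5 (5 adjusted over the list alone, median 0.42, adjusted p = 2.5e-15). B cell markers fell in 7 of 11 cases (8 adjusted over the list alone, median -0.41, adjusted p = 3.1e-05), with Ms4a1 at -0.70 ± 0.14 (-0.47 and no call as the mean of its probe sets) and Fcer2a at -0.62 ± 0.15. Of 14 glucocorticoid and restraint stress genes 3 rose (4 adjusted over the list alone, median 0.23, adjusted p = 1.7e-04), with Ddit4 at 0.64 ± 0.10 and Tsc22d3 at 0.56 ± 0.14. Unfolded protein response genes fell in 2 of 14 cases (5 adjusted over the list alone, median -0.17, adjusted p = 0.0012, and adjusted p = 0.078 with an estimated correlation), with Chac1 at -0.46 ± 0.09. Of 12 p53 targets Fas rose by 0.51 ± 0.09 (3 adjusted over the list alone, median 0.04, adjusted p = 0.0015, and adjusted p = 0.052 with an estimated correlation). Red cell markers moved upward as a list of 4 (median 0.27, adjusted p = 0.041, and adjusted p = 0.24 with an estimated correlation), with 2 called adjusted over the list alone and none over all genes, such as Alas2 at 0.44 ± 0.15.

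Chemokines and cytokines (median 0.09, adjusted p = 0.70), acute phase genes (-0.08, adjusted p = 0.59) and neutrophil markers (-0.01, adjusted p = 0.94) did not move, and Mmp12 differed by -0.18 ± 0.13. NRF2 and aryl hydrocarbon receptor targets had medians between -0.05 and 0.01 whose sign differed from that of the mean or the test, at adjusted p = 0.89 and 0.41.

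Sidestream smoke called 269 genes in regular weight animals, 86 higher and 183 lower, and 7 lists moved. Centring gave 158 higher of 305, and 581 genes were called without the 5 arrays, 1 of which is in this group.

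Sidestream smoke was also compared with air in obese animals. Cyp1a1 was 9.91-fold higher (3.31 ± 0.21, n = 8, adjusted p = 9.4e-16, 8 of 8 arrays). The resistin-like Retnla, a gene of type 2 immunity, was 3.53-fold (1.82 ± 0.18), the vasoconstrictor Edn1 2.54-fold (1.34 ± 0.16) and Slc26a4 2.44-fold higher (1.29 ± 0.20). Zbtb16 was 4.48-fold lower (-2.16 ± 0.27), and Hspa1b and Hspa1a were 3.83-fold (-1.94 ± 0.24) and 2.84-fold (-1.51 ± 0.20) lower.

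All 13 heat shock genes fell, also adjusted over the list alone (median -0.52, adjusted p = 1.7e-11), with Hsph1 at -1.11 ± 0.12. Clock genes peaking with Dbp fell in 8 of 10 cases (8 adjusted over the list alone, median -0.47, adjusted p = 1.2e-08), with Nr1d1 at -1.61 ± 0.12 and Dbp at -1.32 ± 0.16. Those peaking with Bmal1 rose in 2 of 5 (2 adjusted over the list alone, median 0.22, adjusted p = 1.2e-06), with Arntl at 0.60 ± 0.15. Glucocorticoid and restraint stress genes moved downward (2 of 14 higher and 3 lower, 2 and 5 adjusted over the list alone, median -0.22, adjusted p = 0.0026, and adjusted p = 0.13 with an estimated correlation), with Fkbp5 at -1.28 ± 0.15. Unfolded protein response genes fell in 4 of 14 cases (7 adjusted over the list alone, median -0.17, adjusted p = 2.4e-04), such as Herpud1 at -0.40 ± 0.08. Matrix genes rose in 4 of 13 cases (7 adjusted over the list alone, median 0.24, adjusted p = 0.025), with Eln at 0.76 ± 0.16. Rises in 2 of 9 MHC class II genes (5 adjusted over the list alone, median 0.21, adjusted p = 0.049), 2 of 11 B cell markers (2 adjusted over the list alone, median 0.22, adjusted p = 0.043) and 2 of 11 alveolar type 2 markers (2 adjusted over the list alone, median 0.14, adjusted p = 0.049) were also called. With an estimated correlation these 4 lists had adjusted p = 0.42, adjusted p = 0.52, adjusted p = 0.49 and adjusted p = 0.53. All 4 lists lost their calls without the 5 arrays, and no alveolar type 2 marker was then called (median 0.02). Receptor targets moved upward (median 0.04, mean 0.58, adjusted p = 1.2e-07, and 0.067 with an estimated correlation) through 2 of 7, also adjusted over the list alone. They were Cyp1a1 and Cyp1b1 at 0.63 ± 0.14 (0 of 8 arrays above DIO-SC-7, and 0.76 without the 5 arrays).

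The list of acute phase genes did not move (3 of 14 higher, also adjusted over the list alone, median 0.13, adjusted p = 0.052), with Saa3 at 0.83 ± 0.25 and the copper carrier Cp at 0.82 ± 0.12.

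Sidestream smoke called 849 genes in obese animals, 528 higher and 321 lower, and 10 lists moved. Cell cycle genes had a median of 0.03 (adjusted p = 0.89), and without the 5 arrays the list was called (median 0.45, adjusted p = 0.0033).

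The difference between the diets in the sidestream response was tested in the same way. Cyp1a1 responded 14.3-fold more in obese animals (3.84 ± 0.30, n = 8 per group, adjusted p = 1.4e-12). Retnla (1.1 ± 0.26), Edn1 (1.09 ± 0.22), Fcer2a (1.17 ± 0.21) and Ighv14-2 (1.11 ± 0.19) differed upward. Zbtb16 (-2.70 ± 0.38, adjusted p = 2.2e-05), Hspa1b (-2.39 ± 0.34), Fkbp5 (-1.49 ± 0.21) and Klf15 (-1.07 ± 0.20) differed downward. Dbp (1.31 ± 0.23) and Nr1d1 (1.0 ± 0.17) differed upward, so their fall under sidestream smoke was smaller in obese animals.

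B cell markers differed upward in 6 of 11 cases (8 adjusted over the list alone, median 0.65, adjusted p = 1.3e-05), with Ms4a1 at 0.99 ± 0.20. Clock genes peaking with Dbp differed upward in 4 of 10 cases (5 adjusted over the list alone, median 0.22, adjusted p = 0.0076, and adjusted p = 0.20 with an estimated correlation). Those peaking with Bmal1 differed downward (median -0.18, adjusted p = 6.8e-05), with 2 of 5 called adjusted over the list alone and none over all genes, where Nfil3 had -0.70 ± 0.19. Heat shock genes differed downward in 5 of 13 cases (11 adjusted over the list alone, median -0.42, adjusted p = 1.5e-06, and a median of -0.28 without the 5 arrays), such as Dnaja1 at -0.77 ± 0.13. The glucocorticoid and restraint stress genes did so in 3 of 14 (1 higher and 8 lower adjusted over the list alone, median -0.42, adjusted p = 3.5e-06), such as Tsc22d3 at -0.89 ± 0.20. Of 12 p53 targets Fas differed by -0.58 ± 0.12 (1 higher and 3 lower adjusted over the list alone, median -0.11, adjusted p = 3.8e-04). Alveolar type 2 markers differed upward (1 of 11, 7 adjusted over the list alone, median 0.23, adjusted p = 0.015, and adjusted p = 0.20 with an estimated correlation), with Etv5 at 0.62 ± 0.15. Their median was 0.09 without the 5 arrays, and Etv5, at 0.46, lost its call. The receptor's list (median 0.02, mean 0.49, adjusted p = 5.7e-04, and 0.33 with an estimated correlation) rested on Cyp1a1 alone of 7, also adjusted over the list alone.

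In all 81 genes were called, 49 higher and 32 lower, and 8 lists moved. Centring gave 44 higher of 87, and 155 genes were called without the 5 arrays. Over 1345 genes called for the mean of both diets, the sidestream response in obese animals was 1.26 times as large as in regular weight animals (0.257 against 0.204), and it was larger for 840 of them (62.5%, fry adjusted p = 0.10). Over the alternatives this p lay between 1.3e-05, with a ratio of 1.67 over the 27 genes past 1.5-fold, and 0.31, with a ratio of 1.26 without the 5 arrays. Across genes the 2 sidestream responses had r = 0.19 and rho = 0.30, and r = 0.46 without the 5 arrays. Genes called in both were 40 higher and 28 lower, against 3.66 and 4.74 by chance, and 5 went in opposite directions.

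Mainstream and sidestream smoke were compared with each other within each diet. In regular weight animals Saa3 was 41.5-fold (5.38 ± 0.25, n = 8, adjusted p = 9.7e-22, 8 of 8 arrays) and Mmp12 12.7-fold (3.67 ± 0.13) higher under mainstream smoke. Acaa1b (-2.70 ± 0.16) and Fabp1 (-2.12 ± 0.20) were lower. In obese animals Saa3 was 57.0-fold (5.83 ± 0.25, adjusted p = 3.2e-23, 8 of 8 arrays), Cxcl1 19.3-fold (4.27 ± 0.24) and Mmp12 16.9-fold (4.08 ± 0.13) higher, and Acaa1b (-3.12 ± 0.16) was lower. Cyp1a1 differed by -0.16 ± 0.21 and 0.31 ± 0.21 in regular weight and obese animals (adjusted p = 0.71 and 0.34).

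Chemokines and cytokines were higher under mainstream smoke in 13 of 20 cases in regular weight (14 adjusted over the list alone, median 1.18, adjusted p = 2.4e-06) and 19 of 20 in obese animals (19 adjusted over the list alone, median 2.01, adjusted p = 4.9e-11, and a median of 1.33 without the 5 arrays). Interferon response genes did not move (0 and 3 of 16 higher, 0 and 12 adjusted over the list alone, medians 0.19 and 0.79, adjusted p = 0.70 and 0.056). Acute phase genes were higher in 13 and 12 of 14 cases (13 and 13 adjusted over the list alone, medians 1.22 and 1.85, adjusted p = 4.6e-15 and 5.7e-18), with Lcn2 at 2.72 ± 0.12 and 2.67 ± 0.12. Lipid and lysosome genes of macrophages were higher in 10 of 14 cases and lower in 1 in each diet (11 and 10 higher adjusted over the list alone, medians 0.61 and 0.56, adjusted p = 8.8e-18 and 4.2e-17). Cholesterol synthesis genes were higher in 14 and 13 of 15 cases (14 and 13 adjusted over the list alone, medians 0.45 and 0.39, adjusted p = 5.5e-08 and 5.3e-07). Matrix genes were higher in 9 of 13 cases in regular weight animals (10 adjusted over the list alone, median 0.52, adjusted p = 3.6e-06), and in obese animals 9 were higher and 1 lower (10 and 1 adjusted over the list alone, median 0.53, adjusted p = 0.0016, and adjusted p = 0.26 with an estimated correlation). Heme oxygenase, Hmox1, was higher by 0.52 ± 0.12 and 0.43 ± 0.12, with 0.22 and no call in obese animals without the 5 arrays.

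Glutathione transferases were lower in 4 and 8 of 17 cases (9 and 10 adjusted over the list alone, medians -0.17 and -0.24, adjusted p = 0.0029 and 7.1e-05, and adjusted p = 0.26 and adjusted p = 0.18 with an estimated correlation). Pulmonary xenobiotic enzymes were lower in 1 and 7 of 10 cases (2 and 9 adjusted over the list alone, medians -0.15 and -0.38, adjusted p = 0.049 and 1.2e-04, and adjusted p = 0.52 and adjusted p = 0.21 with an estimated correlation). In obese animals the medians of these lists without the 5 arrays were -0.14 and -0.24. The clock genes peaking with Bmal1 were lower in 2 and 3 of 5 cases (2 and 4 adjusted over the list alone, medians -0.24 and -0.31, adjusted p = 4.1e-07 and 4.0e-08), and Arntl had -0.87 ± 0.15 and -0.81 ± 0.15. Those peaking with Dbp were higher in 4 and 3 of 10 cases (4 and 3 adjusted over the list alone, medians 0.16 and 0.16, adjusted p = 0.0027 and 0.049, and adjusted p = 0.25 and adjusted p = 0.50 with an estimated correlation), with Dbp at 1.21 ± 0.16 and 0.85 ± 0.16, and the median in obese animals was 0.27 without the 5 arrays. Unfolded protein response genes were higher in 5 of 14 cases in each diet (7 and 5 adjusted over the list alone, medians 0.16 and 0.13, adjusted p = 0.010 and 5.1e-05, and adjusted p = 0.29 and adjusted p = 0.092 with an estimated correlation). Cell cycle genes were higher in 5 and 12 of 21 cases (16 and 16 adjusted over the list alone, medians 0.64 and 0.62, adjusted p = 0.043 and 0.026, and adjusted p = 0.43 and adjusted p = 0.44 with an estimated correlation).

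In obese animals smooth muscle markers were lower in 6 of 9 cases (8 adjusted over the list alone, median -0.49, adjusted p = 2.2e-04, and adjusted p = 0.24 with an estimated correlation) and MHC class II genes higher in 7 of 9 (8 adjusted over the list alone, median 0.37, adjusted p = 6.8e-05, and adjusted p = 0.12 with an estimated correlation). Neutrophil markers were higher in 5 of 14 (5 adjusted over the list alone, median 0.15, adjusted p = 0.0045, and adjusted p = 0.35 with an estimated correlation) and heat shock genes in 3 of 13 (5 adjusted over the list alone, median 0.13, adjusted p = 0.049, and adjusted p = 0.49 with an estimated correlation). The neutrophil median was -0.08 without the 5 arrays, and the heat shock median was 0.07 with the call lost. Glucocorticoid and restraint stress genes moved upward (4 of 14 higher and 2 lower, 5 and 2 adjusted over the list alone, median -0.01, mean 0.23, adjusted p = 0.0037, and adjusted p = 0.56 with an estimated correlation), with Mt2 at 0.96 ± 0.16 and most of the mean from Lcn2 at 2.67. Aryl hydrocarbon receptor targets had a median of 0.10 (adjusted p = 0.046, and adjusted p = 0.44 with an estimated correlation), and no member was called, with Cyp1b1 at 0.39 ± 0.14 (adjusted p = 0.055). In regular weight animals the alveolar macrophage list moved (4 of 12 higher and 4 lower, the same adjusted over the list alone, median 0.01, adjusted p = 0.0058, and adjusted p = 0.77 with an estimated correlation), with Marco at 2.18 ± 0.16. Whether these differences between the smokes differ between the diets was not tested.

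Mainstream against sidestream smoke called 1211 genes in regular weight animals, 750 higher and 461 lower, with 12 lists moved, and 2086 in obese animals, 1094 higher and 992 lower, with 17 lists moved. Without the 5 arrays 2116 and 1482 were called.

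Across genes the responses to the 2 smokes had r = 0.39 (rho = 0.46, covariance 0.0143) in regular weight and r = 0.53 (rho = 0.52, covariance 0.0335) in obese animals. They share their 8 air arrays. With the air arrays dealt 4 and 4, r was 0.23 and 0.23 and the covariance 0.0096 and 0.0176, and simulated unchanged groups with shared air arrays gave r = 0.47 and a covariance of 0.0057. Genes called in both numbered 31 higher and 98 lower in regular weight animals, against 5.68 and 14.8 by chance with arrays not shared, and 235 and 199 in obese animals, against 61.7 and 31.3.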

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

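The Cyp1b1 test of smoke-exposed air arrays, the Rag1 test of thymus and the counts of where splits put the arrays were chosen only after their results had been seen, the other tests of explanations after the patterns but before their results, and the splits into chance groups before both.

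Cyp1a1 was lower in obese than in regular weight animals breathing air. Tissue carried over in the 5 arrays that stand apart is excluded, as the difference without them was -4.86. Less activity of the aryl hydrocarbon receptor cannot be told apart from a change of Cyp1a1 alone. Fry, a rotation test and not a permutation test, gave p = 0.984 over the 6 other targets. None was called, but without the 5 arrays Cyp1b1 was (-0.31). Smoke-exposed animals among the regular weight air arrays are excluded by Cyp1b1, whose highest signal there was 7.70 against a lowest of 7.81 in the 16 regular weight smoke arrays, a narrow margin. Diet composition is another candidate, because plant compounds in feed can activate the receptor. This, obesity and tissue in other arrays were not tested.

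Heat shock genes were higher and Cirbp lower in obese than in regular weight animals breathing air. Tissue carried over in the 5 arrays is excluded, because the median of the 13 called genes was 0.62 without and 0.63 with them, and all 13 were still called. Another hour of necropsy cannot be told apart from no such difference, as the larger p of the 2 clock lists in fry, a rotation test and not a permutation test, was 0.725 and the smaller was 5.5e-04. A higher body temperature or more stress in the nose-only tubes may have raised the chaperones and lowered Cirbp in obese animals. The diet may have acted otherwise, and these and tissue in other arrays were not tested.

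Genes induced by interferon were far higher in arrays DIO-MS-1 and DIO-MS-6 than in the other 6 of their group. Animals that had no mainstream smoke are excluded, as the scores of these arrays on the regular weight mainstream response were 4.49 and 4.97 against at most -0.65 in the 32 arrays without such smoke. Thymus or lymphoid tissue carried over is left open, because their thymocyte scores were 0.73 and 0.47 against at most -0.16 in the other 6, and their T cell scores 1.13 and 0.69 against at most -0.07, while their B cell scores of 0.11 and -0.0035 hardly passed the -0.0045 there. Thymus itself is excluded, as their Rag1 signals were 3.46 and 3.25 against up to 3.78 in the other 6 and 12.37 in DIO-SC-7, whose interferon score was -0.20 beside a T cell score of 3.10. A viral infection or a stronger immune response to smoke in these animals may explain the genes, and neither was tested.

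Splits of the same arrays into chance groups, 100 for each contrast, asked whether chance can be excluded. The value is the number of groupings, the real one included, that did as well as the real one. For genes called it was 2 for diet (1026 real, 1037 highest other), 1 for mainstream smoke in regular weight animals (1819, 532) and 1 in obese animals (2658, 1427). It was 1 for sidestream smoke in regular weight (269, 263) and 1 in obese animals (849, 36), and 2 and 1 for the differences between the diets under mainstream (110, 282) and sidestream smoke (81, 2). For mainstream against sidestream smoke it was 1 in regular weight (1211, 57) and 1 in obese animals (2086, 1366). For lists moved in the same order the values were 2 (11, 12), 1 (15, 9), 1 (18, 14), 2 (7, 7), 1 (10, 7), 1 (10, 9), 1 (8, 5), 1 (12, 6) and 1 (17, 15). This share of at most 2 in 100 argues against chance, except for sidestream smoke in regular weight animals. A simulation of that contrast called 394 unchanged genes, more than the 269. The other split with 1366 genes left 14 of 16 arrays in their own group and may reflect the real grouping. Those with 1037, 1427 and 263 left 8, 10 and 8 there, and the 32, 51 and 38 other splits that left as many called a median of 0 genes and at most 805, 1013 and 138. Those with 1037, 1427 and 1366 had the arrays that stand apart on 1 side, as 47, 5 and 44 splits did. Splits that parted them called at most 70, 1113 and 161. These and the 282 for the mainstream difference (residuals of an additive model dealt among 32 arrays) may point to sample structure besides the groups. The arrays that stand apart may have a part in it for diet and between the smokes in obese animals. Its source was not tested further.

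A Dixon test of the gap to the nearest array of a group drew out single arrays, by chance in about 1 group in 20. It found 39 of 318 (2 of 18 array measures, 9 of 66 indicator genes, 28 of 234 list scores). The thymocyte, squamous and brown fat lists hold top genes of such arrays, so chance cannot be judged. Array RW-SS-6 had a mean correlation of 0.982, a log2 signal of Cyp1b1 of 8.64 and of Scd1 of 14.19, and scores of 4.00 for adipocyte, 3.89 for brown fat, 1.29 for fatty acid oxidation, 1.07 for fatty acid synthesis, -0.29 for alveolar type 2 and -0.27 for alveolar type 1 genes. Array DIO-SC-7 had a Cyp1b1 signal of 8.41 and scores of 5.15 for thymocyte, 3.10 for T cell, 2.46 for cell cycle, 1.76 for fatty acid oxidation, -0.36 for glutathione transferase, -0.78 for alveolar type 1 and -0.68 for endothelial genes. Array DIO-SC-3 scored 5.12 for skeletal muscle and 5.98 for squamous epithelium, and DIO-MS-1 -0.98 for brown fat.

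In regular weight animals under mainstream smoke RW-MS-5 had signals of 9.61 for Hmox1 and 9.38 for Mmp12 and scores of 0.061 for chemokines and 0.65 for cholesterol synthesis. RW-MS-7 had an Nqo1 signal of 6.86 and scores of -0.15 for MHC class II, 1.48 for interferon and -0.41 for ciliated cell genes, and RW-MS-6 scored -0.11 for the unfolded protein response. Among regular weight air arrays RW-SC-5 had an S100a8 signal of 12.03, RW-SC-6 a Dbp signal of 11.15 and RW-SC-4 an interferon score of 0.85. Under sidestream smoke RW-SS-8 had a Cyp1a1 signal of 10.14 and an interferon score of 0.50, and RW-SS-7 a Gapdh 3′ minus 5′ signal of 0.018. In obese animals under sidestream smoke DIO-SS-3 scored 0.20 for receptor targets, DIO-SS-5 -0.25 for chemokines, DIO-SS-6 0.57 for immediate early genes and DIO-SS-1 0.015 for the unfolded protein response.

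Responses that differed between the diets were drawn out because a direct test called them. For mainstream smoke they were 110 genes and 10 lists. The named genes were Cyp1a1 (4.31), Orm2 (1.42), Saa3 (1.38), Saa1 (1.35), Hpx (1.09), Fcer2a (1.08), Dbp (0.95), Ccr7 (0.92), Nr1d1 (0.89), Fpr2 (0.82), Cp (0.75), Mmp12 (0.71), Etv5 (0.70), Ciita (0.69), Blnk (0.55), H2-Eb1 (0.54) and H2-Ab1 (0.53) upward. Downward were Hspa1b (-2.12), Hspa1a (-1.77), Zbtb16 (-1.59), Egln3 (-1.35), Actg2 (-1.04), Cnn1 (-0.98), Dnaja1 (-0.72), Chordc1 (-0.72), Acta2 (-0.66), Tagln (-0.52), Phlda3 (-0.44) and Idi1 (-0.43). Leaving out the 5 arrays gave 0.77 for Orm2 and -0.81 for Egln3, and Saa3, Cp (0.47), Mmp12, Fpr2 (0.39), Ciita, Blnk, Cnn1, Acta2, Tagln and Phlda3 lost their calls. The list medians were 0.72 for acute phase, 0.53 for MHC class II, 0.47 for B cell, 0.22 for alveolar type 2 and 0.20 for receptor genes, and -0.63 for smooth muscle, -0.36 for heat shock, -0.32 for glucocorticoid, -0.32 for Bmal1 clock and -0.16 for p53 genes.

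For sidestream smoke they were 81 genes and 8 lists. Upward were Cyp1a1 (3.84), Dbp (1.31), Fcer2a (1.17), Ighv14-2 (1.11), Retnla (1.1), Edn1 (1.09), Nr1d1 (1.0), Ms4a1 (0.99), Cd79a (0.82), Cd79b (0.81), Cp (0.71), Etv5 (0.62), Nr1d2 (0.59) and Per3 (0.59). Downward were Zbtb16 (-2.70), Hspa1b (-2.39), Hspa1a (-1.85), Fkbp5 (-1.49), Egln3 (-1.46), Klf15 (-1.07), Tsc22d3 (-0.89), Dnaja1 (-0.77), Hsph1 (-0.75) and Fas (-0.58). Leaving out the 5 arrays gave -0.76 for Egln3, which also lost its call without RW-SS-6 alone, and Cp (0.52) and Etv5 (0.46) lost their calls. The list medians were 0.65 for B cell, 0.23 for alveolar type 2, 0.22 for Dbp clock and 0.023 for receptor genes, and -0.42 for heat shock, -0.42 for glucocorticoid, -0.18 for Bmal1 clock and -0.11 for p53 genes. The air groups differ for many of these genes, so each difference between responses contains the difference in air with the opposite sign.

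The 2246 probe sets without exactly 1 symbol were drawn out because they hold results that the named genes leave aside. Those called were 80 for diet, 221 and 274 for mainstream smoke in regular weight and obese animals, 21 and 53 for sidestream smoke, 13 and 12 for the differences between the diets and 147 and 196 for mainstream against sidestream smoke.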

How the results depend on the processing

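The number of arrays per group and the sharing of air arrays limit every comparison, and the 5-array alternative was chosen after seeing the data. Signal over background could not be examined without raw scans, which limits what is said of dim genes. The cause was not tested for any value below unless the construction of the alternative shows it.

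A fit to only the groups of the contrast, which leaves fewer arrays to estimate the spread, called fewer genes, 312 for diet, 1178 for mainstream and 380 for sidestream smoke in obese animals and 35 for the mainstream difference between the diets. Testing every probe set called 2990 probe sets for mainstream and 494 for sidestream smoke in regular weight animals, as there were more to call. Array weights gave 638 genes for sidestream smoke in regular weight and 1295 in obese animals, 136 for the sidestream difference and 2169 for mainstream against sidestream smoke in regular weight animals. Leaving out the 5 arrays gave 3015, 581, 155 and 2116 genes for mainstream and sidestream smoke in regular weight animals, the sidestream difference and mainstream against sidestream smoke in regular weight animals.

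Camera with an estimated correlation called 3 lists for diet, 7 and 5 for mainstream smoke in regular weight and obese animals, 4 and 4 for sidestream smoke, 9 and 5 for the mainstream and sidestream differences, and 6 and 5 for mainstream against sidestream smoke. With a preset correlation it called 13 and 20 for sidestream smoke in regular weight and obese animals and 23 and 17 for the differences. Without the 5 arrays 12 lists moved for sidestream smoke in regular weight animals. Single lists kept their call or lack of it in 264 of 324 cases with the estimated correlation (60 lost), 263 with the preset one (54 gained, 7 lost) and 286 without the 5 arrays (27 gained, 8 lost, 3 reversed).

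The ratio of sizes was 1.39 for mainstream and 1.67 for sidestream smoke over genes past 1.5-fold. The correlation of the sidestream responses in the diets was 0.458 without the 5 arrays, and that of the responses to both smokes was 0.232 in regular weight and 0.226 in obese animals with the air arrays dealt 4 and 4, which removes the shared arrays. Without the 5 arrays T cell markers fell with diet (adjusted p = 2.4e-04), endothelial markers fell with sidestream smoke in obese animals (adjusted p = 0.0073) and T cell markers differed upward between the sidestream responses (adjusted p = 0.020), each reversed in direction. Nqo1 was 0.018 in place of a fall under mainstream smoke in obese animals without the 5 arrays, and Cpt1a was 0.0002 under mainstream smoke in regular weight animals as the mean of its probe sets. Among named genes 25335 values stayed called or stayed not called, 154 gained a call and 1109 lost it.

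Leaving out each array in turn gave 750 to 1418 genes for diet, 1342 to 1859 and 2092 to 3073 for mainstream smoke in regular weight and obese animals, 144 to 361 and 654 to 1079 for sidestream smoke, 50 to 195 and 63 to 138 for the mainstream and sidestream differences, and 888 to 1259 and 1388 to 2259 for mainstream against sidestream smoke. The count for sidestream smoke in regular weight animals was 167, 144, 160 and 176 without RW-SC-1, 3, 4 and 8 and 157 without RW-SS-6. The mainstream difference had 50, 68, 68 and 66 genes without RW-SC-3, 4, 5 and 8, 71, 66, 186 and 195 without DIO-SC-2, 3, 4 and 7, 57 and 70 without RW-MS-1 and 3, and 69 without DIO-MS-1. The sidestream difference had 138 without DIO-SC-7, and mainstream against sidestream smoke in obese animals 1388 without DIO-MS-1. A replicate block, which treats arrays of the same number as belonging together although some of those numbers are in doubt, called 1022, 1753, 2616, 269, 822, 98, 80, 1186 and 2037 genes in the order above.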

Other observations

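The readings below and the choice of the 5 arrays were made after the results had been seen. The Cyp1a1 values set the diets apart before any smoke, and under both smokes obese animals rose towards, but stayed below, the 9.58 that regular weight animals had in air. The mean log2 signal was 8.36 and 8.05 in obese animals under mainstream and sidestream smoke, and 8.89 and 9.04 in regular weight animals. Without the 5 arrays the difference in air was -4.86, so the large difference between the responses may largely reflect the starting level. The same holds for the heat shock genes, whose median in air was 0.62 higher without the 5 arrays and whose levels fell under both smokes in obese animals.

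Under both smokes and in both diets fry called the clock genes peaking with Dbp lower, with the lowest median under sidestream smoke in regular weight animals, where Dbp fell by 2.62 and Arntl rose by 1.40. Under mainstream smoke in obese animals the Bmal1 clock list did not move (median -0.06, adjusted p = 0.37), and the Dbp list had adjusted p = 0.20 with an estimated correlation. The hour of necropsy is not given in the sources used here. A shift of the clock by smoke and a different hour of collection for some groups may give the same pattern, and the p of 0.725 for the larger of the 2 clock lists in air, from fry, a rotation test and not a permutation test, bears only on the air groups.

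The inflammatory response to mainstream smoke was present in both diets and differed upward in obese animals for acute phase and MHC class II genes. Part of the acute phase difference came with DIO-MS-1 and DIO-MS-6, as its median was 0.37 without the 5 arrays. The MHC class II difference contains a lower start, with scores of -0.26 in obese and 0.06 in regular weight animals in air and 0.25 and 0.08 under mainstream smoke, the 0.25 resting in part on DIO-MS-1 and DIO-MS-6 (0.54 and 0.45 against 0.11 to 0.24 in the other 6). The overall size ratio of 1.31 became 1.1 without the 5 arrays, so part of it may rest on arrays such as DIO-MS-1 and DIO-MS-6. Of the title's oxidative stress response, NRF2 targets did not move in 1 direction as a list in any contrast. Under mainstream smoke members were called both higher, such as Slc7a11, and lower, which a test of 1 direction can miss. Fry called glutathione transferases lower under mainstream smoke in obese animals and against sidestream smoke in both diets. An estimated correlation kept none of these calls. Markers of dose were not analysed, so a difference in dose between diets or smokes is not excluded.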
